A study of Homo sapiens with 2 samples.

How the data were processed

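MicroRNA (miRNA) levels were measured in total RNA of SK-HEP-1 cells, an established human cell line that the labels call a liver cancer line, with a 1-colour (Cy3) Agilent human miRNA array. 1 library came from untreated cells and 1 from cells given 5 µM 5-azacytidine for 24 h. The labels place both hybridisations on the same slide, so slide does not separate the groups. The untreated library was grown under a protocol shared with several other cell lines, and the labels do not say whether both libraries came from the same culture. With 1 library per group no test between conditions was possible, and no p-value was computed.

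Values of both arrays came from the deposited value table, which held 723 human miRNAs. Its deposited values are on a log2 scale, as found by setting the treated column against the scanner file of that array. The treated column increased with the log2 total gene signal without exception (rank correlation 1 across miRNAs), and every miRNA with a scanner signal of 0.999 or less stood at the column's lowest value, while the next signal, 1.00, stood above it. Both columns had the same maximum (14.11 log2) and 92.7% of the distinct untreated values also occurred in the treated column, so the authors' deposited values had been through a normalization of the quantile type, in which rank sets the value. The step itself, and the arrays over which it was made, are not given in the sources used here. The column medians were 0.47 log2 (untreated) and 0.25 log2 (treated), which are also the lowest values of the columns, because 506 untreated and 432 treated values stood at them. The third-highest treated value did not occur in the untreated column. The lowest value above this shared minimum was 2.25 log2 on the untreated array and 1.36 log2 on the treated array.

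The deposited scanner file of the treated array holds linear intensity values, which per the file headers were made with Agilent Feature Extraction 10.5.1.1, which subtracted background, removed spatial trends and summed the probes of a miRNA into a total gene signal with an error from its replicate spots. Each miRNA had 16 to 17 spots and 1 to 4 probes, and 0 spots of human miRNAs were saturated. Detection flags are those of the same software. The scanner file of the untreated array was not used here. The median error of the total gene signal was 8.20% for signals of 10 or more and 35.1% for signals from the floor up to 10. The number of arrays limits the precision, and these errors cover replicate spots of 1 array only.

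The following choices were made before the data were examined. Columns whose 75th percentiles differed by less than 5% were to be used as deposited; they were 2.86 and 2.75 log2, a difference of 4.09% of the log2 values, so no further scaling was applied. The rule did not name a scale, and it was met on the log2 scale alone, since the same gap of 0.11 log2 is 8.28% in intensity; scaling by it is among the alternatives. The floor was the lowest treated value among human miRNAs flagged as detected, 1.72 log2 (a scanner signal of 1.39), used for both arrays because detection flags were at hand for the treated array alone. A second part of the floor rule, based on viral miRNAs in the value table, was not applied because the table used here had no viral rows. Of the 252 treated values at or above the floor, 78 were not flagged as detected. Differences are treated minus untreated on the log2 scale, and a miRNA was counted as higher or lower when it was above the floor on both arrays and differed by 2-fold or more. For a miRNA above the floor on 1 array alone only a bound ("at least N-fold") was computed. For miRNAs above it in the treated library alone, the bound was set against 2.25 log2, the lowest measured untreated value, because that is higher than the floor and so gives the smaller fold; this departs from the rule as first written, which used the floor. For miRNAs above it in the untreated library alone the bound was set against 1.72 log2. After the data were seen, these bounds were replaced in the text by bounds against 3.36 log2, the level from which every human miRNA was flagged as detected on the treated array. The same level bounds, in either direction, the miRNAs 2-fold apart whose treated value was not flagged as detected or whose untreated value lay under it. Differences of other named miRNAs not flagged as detected on the treated array were withheld. Counts of higher and lower miRNAs, list medians and list counts keep the floor fixed in advance and so include 33 miRNAs above it on both arrays that were not flagged as detected.

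The named miRNAs were chosen by a rule fixed in advance: up to 12 with the largest difference in each direction among those 2-fold or more apart, the 6 largest bounds in each direction, the 6 highest values of each array, and up to 4 members of each list with the largest difference. In all, 18 lists of miRNAs (families, genomic clusters and cell type markers) were fixed in advance, with all mature arms of a member counted. For the 7 lists with 5 or more members above the floor on both arrays, the median difference was placed among 10000 random lists of the same size matched on mean level in 5 bins; this percentile describes these libraries and is not a test of the treatment. The range given with it holds the central 95% of the random medians.

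The comparison was tested on simulated data made for the 723 miRNAs of the treated against untreated comparison. In 1000 simulations, 2 arrays were drawn from the treated array's signals and their spot errors, assuming the same errors for the untreated array and no difference between cells. Both simulated arrays were given the values of the treated column by rank. In a further 100 simulations of 24 changed miRNAs each, 85.8% of planted differences of 1.5 log2 were found, 95.6% of those of 2 log2 and 98.6% of those of 3 log2. A miRNA counted as found when it was 2-fold apart in the planted direction. It also counted when above the floor on 1 simulated array only in that direction, which is looser than the fixed rule. Changes were planted only in miRNAs with treated signals well above the floor, so recovery among dimmer miRNAs was not measured.

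Alternatives comprised scaling to the 75th percentile or median of miRNAs above the floor on both arrays, scaling to the 75th percentile of all human miRNAs, quantile normalization of the 2 columns, a floor 4 times higher, thresholds of 1.5-fold and 3-fold, a pseudocount equal to the floor in its place, the strongest arm of each list member, and, for the treated array, a normexp background correction of spot means with limma (offset 0, leaving out 974 outlier spots of 12784). A floor from detected miRNAs without viral ones was also listed, and equals the floor used. 3 further floors were chosen after seeing the data. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1.

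Positions are those of the array's probe targets in the scanner file, on human genome build hg18 per the file headers. miRNA names are those of the array design. Through a gene table of a later assembly (GRCh38.p14), 641 of the 723 miRNAs were matched to 1 gene on the same chromosome; that table was used for gene names and for which genes span a miRNA gene, on either strand, and none of its coordinates are given. Names that stand for several gene copies were left unmatched. Probe sequences were not used here, so signal shared between near-identical miRNAs, such as let-7 members, cannot be separated.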

Results

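The series compared miRNA levels in SK-HEP-1 cells with and without 5-azacytidine, a cytidine analogue that inhibits DNA methyltransferases, to find miRNAs whose level differed with the drug. 1 untreated library and 1 library treated with 5 µM 5-azacytidine for 24 h were measured, so no difference below has a replicate check, and a size rule stands in place of a test. Of 723 human miRNAs on the array, 217 were above the floor in the untreated library and 252 in the treated library. The summed signal of the treated array was 24565 intensity units, of which 45.7% came from miR-21.

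The same 6 miRNAs had the highest values on both arrays. miR-21, an abundant miRNA of many cancer lines whose gene lies within VMP1, stood at 14.11 log2 on each. miR-923, a name used for a fragment of ribosomal RNA, stood at 11.79 log2 on each and let-7i at 10.95 log2 on each. Equal values here mean equal places among the shared values of the normalization, not equal amounts or equal ranks. let-7i stood above let-7a in the untreated library and below it in the treated library. Its values are equal because the untreated column lacks the third-highest treated value. That gap also enters the differences of miR-23a, let-7a and let-7f. miR-23a was 10.73 log2 untreated and 10.51 log2 treated, let-7a 10.51 and 11.13 log2, and let-7f 10.29 and 10.73 log2.

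Among the miRNAs above the floor on both arrays, which were 26.7% of the 723, 6 were at least 2-fold higher and 11 at least 2-fold lower in the treated library, and 176 (91.2%) lay within 2-fold. The treated signal was flagged as detected for all 6 of the higher miRNAs and for 6 of the 11 lower ones. Flags were at hand only for the treated array, on which higher miRNAs are the brighter by definition, so these shares cannot be compared. The split moved with the floor and the scaling. With both arrays read from 2.25 log2 upward, a floor chosen after seeing the data, 6 were higher and 8 lower. No untreated value lay between the floor and 2.25 log2, so treated values in that range could add lower calls only. With both arrays scaled to the 75th percentile of all human miRNAs, which shifted every difference by 0.11 log2, 7 were higher and 8 lower, and with quantile normalization of the 2 columns 7 were higher and 6 lower. The median difference was -0.06 log2 and its standard deviation across miRNAs 0.59 log2. Across these miRNAs, which are not independent replicates, the values of the arrays had a Pearson r of 0.97 and a Spearman rho of 0.95. Differences were wider among dim miRNAs. The standard deviation was 0.73 log2 for untreated levels under 5 log2 and 0.40 log2 for the 98 miRNAs at 5 log2 or more, of which 0 were 2-fold higher and 3 were 2-fold lower. Simulated pairs of arrays that differed only by the spot error of the treated array gave a median of 3 higher miRNAs (central 95%, 1 to 7) and 3 lower (1 to 7), or 7 in either direction (3 to 12), against the 17 measured. The 6 higher lie within the simulated range and the 11 lower above it. Both simulated arrays took the treated column's values, down to 1.36 log2, and so lack the untreated array's gap below 2.25 log2. The simulation therefore does not match the data for dim miRNAs.

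**Figure D1:**
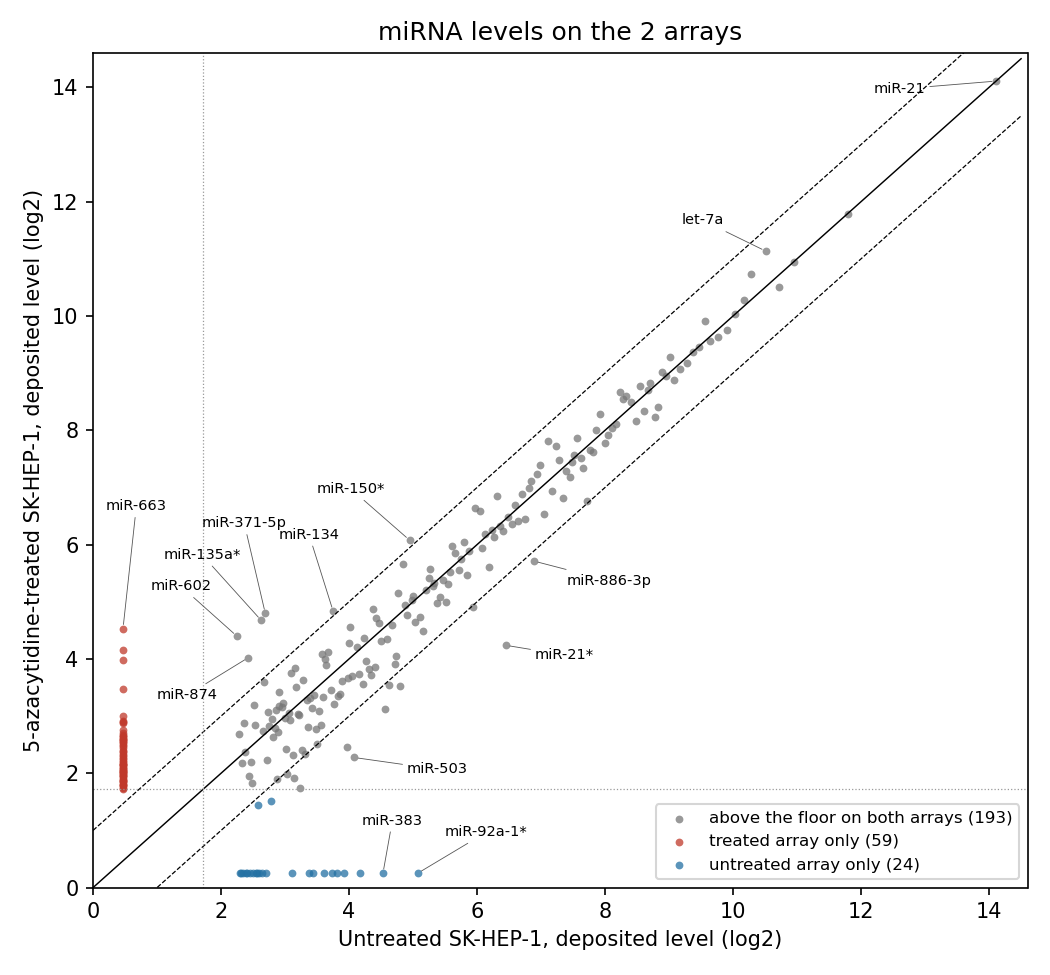
Each point is 1 miRNA, with its deposited log2 level in the untreated library on the x axis and in the treated library on the y axis; solid line, equal values; dashed lines, 2-fold; dotted lines, the floor of 1.72 log2. Of the miRNAs above the floor on both arrays (grey) 91.2% lie within 2-fold, while 59 (red) and 24 (blue) were above the floor in the treated or the untreated library alone.

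The 6 higher miRNAs were all dim in the untreated library, at 4.95 log2 or less. miR-150* was 2.19-fold higher in the treated library (4.95 log2 untreated and 6.08 log2 treated) and miR-134 2.12-fold higher (3.75 and 4.84 log2); the star marks the arm of a precursor that was first held to be the less abundant. The other 4 had untreated values under 3.36 log2, the level from which every miRNA was flagged as detected on the treated array (chosen after seeing the data), and no detection flag was at hand for the untreated array, so they are given as bounds against that level. miR-371-5p, from a cluster active in embryonic stem cells, was at least 2.71-fold higher (2.69 and 4.80 log2) and miR-135a* at least 2.49-fold higher (2.63 and 4.68 log2). miR-602 was at least 2.06-fold higher (2.25 and 4.40 log2), its untreated value being the lowest measured on that array, and miR-874 at least 1.58-fold higher (2.42 and 4.02 log2). All 6 were flagged as detected on the treated array, where the spot error of their signals was 6.24% to 18.6%. Their probe targets span 13 to 15 bases, at the short end of the array. The partner arms miR-150 and miR-371-3p stood at the lowest value of each array, so the partner arms give no second reading of those precursors. On build hg18, the target of miR-602 lies on chromosome 9 at 139852715 to 139852729, that of miR-371-5p on chromosome 19 at 58982753 to 58982765, and that of miR-135a* on chromosome 3 at 52303288 to 52303300. The miR-874 target is on chromosome 5 at 137011170 to 137011182, and its gene is spanned by KLHL3. Targets of miR-150* and miR-134 lie on chromosome 19 at 54695866 to 54695878 and on chromosome 14 at 100590793 to 100590805. With a floor 4 times higher, which leaves out the miRNAs dim on either array, 2 remained, miR-150* and miR-134.

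**Figure D2:**
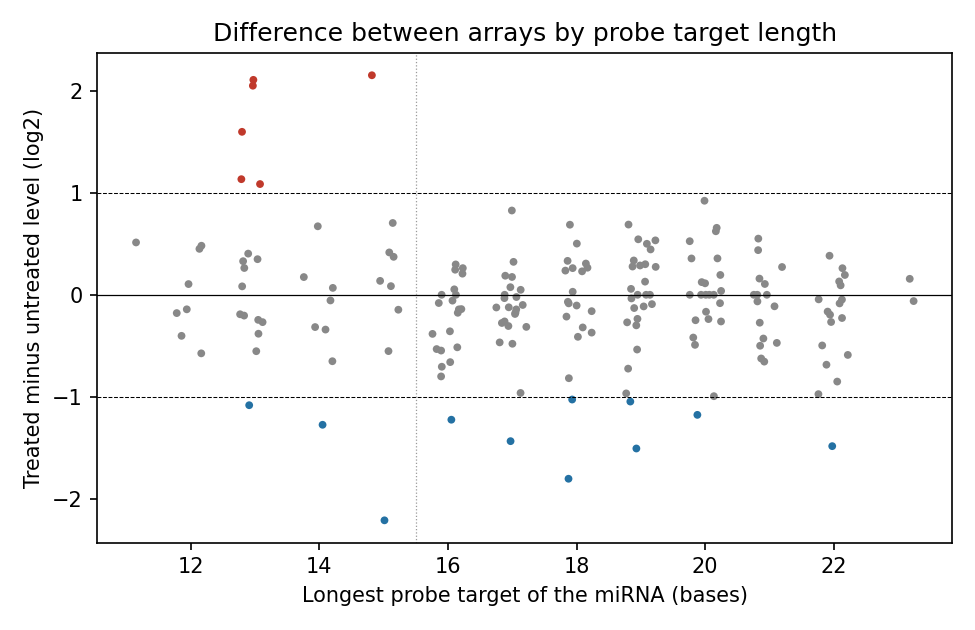
Treated minus untreated log2 difference of each miRNA above the floor on both arrays (y axis) against the length in bases of its longest probe target (x axis, points spread sideways by a random part of a base); red, 2-fold or more higher; blue, 2-fold or more lower; dashed lines, 2-fold. All 6 higher miRNAs lie at 13 to 15 bases, left of the dotted line, while 3 of the 11 lower ones do.

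The largest difference in the other direction was that of miR-21*, the partner arm of miR-21. It was 6.45 log2 untreated and 4.24 log2 treated, 4.63-fold lower, whereas miR-21 itself held the shared maximum of the normalization on both arrays. Its target is on chromosome 17 at 55273460 to 55273474 (hg18). Both miR-181a partner arms were lower, miR-181a-2* by 2.70-fold and miR-181a* by 2.04-fold. The treated value of miR-181a-2*, 3.13 log2, was flagged as detected but lay under the level of full detection, with a spot error of 23.2%. miR-886-3p, which derives from the vault RNA gene VTRNA2-1 on chromosome 5 (target 135444087 to 135444106), was 2.26-fold lower (6.89 and 5.71 log2). miR-877*, spanned by ABCF1, was 2.42-fold lower, and miR-1237, spanned by RPS6KA4, 2.12-fold. On the treated array miR-1237 was flagged as detected, although 0 of its 16 spots were marked as well above background. The spot error of the treated signal was 17.6% for miR-21* and 8.96% for miR-886-3p. The other 5 of the 11 were not flagged as detected on the treated array, where their errors were 51.3% to 62.0%, so their size is not measured. Against the same level of full detection, 3.36 log2, miR-503, a member of the miR-15/16 family that restrains the cell cycle, was at least 1.65-fold lower (4.08 log2 untreated; target on chromosome X at 133508067 to 133508084, within the host transcript MIR503HG). miR-363, from the X-linked copy of the miR-17 to 92 clusters, was at least 1.52-fold lower (3.96 log2 untreated; target on chromosome X at 133131078 to 133131096, within MIR106AHG). miR-16-2*, miR-935 and miR-625*, at 3.23, 3.14 and 3.03 log2 untreated, lie below that level on both arrays and have no fold. With a floor 4 times higher 3 remained, miR-21*, miR-886-3p and miR-181a*. Scaling took some calls under 2-fold. miR-181a* was -0.97 log2 when scaled to the median of miRNAs above the floor on both arrays. Scaled to the 75th percentile of all human miRNAs, miR-181a* was -0.91 log2 and miR-1237 -0.97 log2.

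A further 59 miRNAs were above the floor in the treated library only and 24 in the untreated library only. These counts depend on the unequal lowest measured values of the arrays. With both arrays read down to 2.25 log2, a floor chosen after seeing the data, they were 29 and 33. The shared values of the normalization make counts above a shared level nearly equal. Simulated pairs of arrays that differed by spot error alone gave 46 in each direction (central 95%, 39 to 53), with 59 above and 24 below that range. Spot error alone thus gave many miRNAs above the floor on a single array. Both simulated arrays took the treated column's values and so shared its lowest measured value. The simulation therefore cannot speak to the unequal split of 59 and 24. Of the 59, 14 were flagged as detected, and 28 exceeded the lowest measured untreated value, of which 4 did so by 2-fold or more, all flagged as detected. Against the level of full detection 1 of these was 2-fold or more higher. On those terms miR-663 was at least 2.25-fold higher in the treated library (4.53 log2 there; target on chromosome 20 at 26136879 to 26136891, within MIR663AHG). miR-629* was at least 1.73-fold higher, miR-192, a miRNA of liver and kidney that p53 induces, at least 1.54-fold higher (3.98 log2; target on chromosome 11 at 64415251 to 64415269, within MIR194-2HG) and miR-1233 at least 1.09-fold higher, while miR-423-3p and miR-513b lay below that level and have no fold. Of the 24, 0 were flagged as detected on the treated array, which follows from construction because the floor is the lowest flagged value there. Against the level of full detection, 3.36 log2, 2 had a bound of 2-fold or more. Against the floor fixed in advance, 11 did. miR-92a-1*, from the miR-17 to 92 host transcript MIR17HG, was at least 3.29-fold lower in the treated library against the level of full detection (5.08 log2 untreated; target on chromosome 13 at 90801584 to 90801601). On the same terms miR-383, spanned by SGCZ, was at least 2.25-fold lower, miR-607 at least 1.75-fold, miR-651 at least 1.47-fold, miR-30d* at least 1.37-fold and miR-325 at least 1.30-fold.

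The let-7 family, which represses growth-promoting genes and is low in many tumours, was the list that stood farthest from random lists. Of its 11 members above the floor on both arrays, 9 were higher, 1 lower and 1 equal, and 0 differed by 2-fold. The median difference was 0.34 log2, at percentile 99.9 of matched random lists (range -0.19 to 0.23). let-7a differed by 0.62 log2, miR-98 by 0.55 log2, let-7d by 0.44 log2 and let-7f-1* by 0.92 log2, the last from an untreated value of 2.68 log2, below the level of full detection. The family median stayed between 0.30 and 0.45 log2 under every scaling, but with quantile normalization of the 2 columns let-7i went from 0 to -0.20 log2, let-7a from 0.62 to 0.42 log2 and let-7f from 0.44 to 0.22 log2, and outside the family miR-23a from -0.21 to -0.44 log2. Mature let-7 members are nearly identical in sequence, so their values are not independent of each other and the split between members is uncertain.

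**Figure D3:**
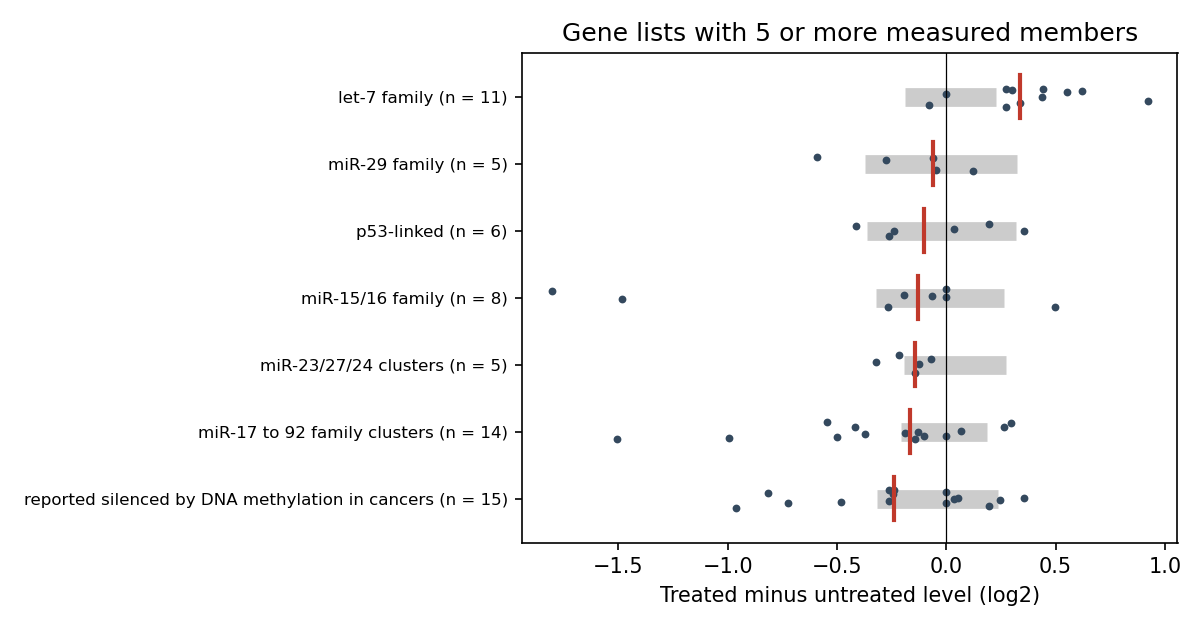
Treated minus untreated log2 difference of each miRNA above the floor on both arrays (points), for the 7 lists with 5 or more such members; red bars are list medians and grey bands the central 95% of medians of 10000 matched random lists. The let-7 median of 0.34 log2 lies above its band of -0.19 to 0.23, and the other medians lie within theirs.

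Of 45 arms on the list of miRNAs reported to be silenced by DNA methylation in cancers, 15 were above the floor on both arrays and 0 of these differed by 2-fold. 5 were higher, 8 lower and 2 equal, with a median of -0.24 log2 at percentile 12.8 (range -0.32 to 0.24). Scaled to the 75th percentile of all human miRNAs, 7 were higher and 8 lower, with a median of -0.12 log2. With the floor 4 times higher the median was 0. Of the 15, 3 were not flagged as detected on the treated array, among them miR-126 and miR-129-3p, whose signals there had errors of 59.8% and 41.5%. miR-193a-3p differed by -0.96 log2 and miR-200b by -0.48 log2. A further 7 were above the floor in the treated library only, of which 0 were flagged as detected, and 2 in the untreated library only. miR-34a, a p53 target often methylated in tumours, was 8.67 log2 untreated and 8.71 log2 treated. Of 17 arms on the p53-linked list, 6 were above the floor on both arrays, 3 in the treated library only and 0 in the untreated library only. Of those 3, miR-192 alone was flagged as detected. Among the 6 measured on both arrays, 3 were higher and 3 lower, with a median of -0.10 log2 at percentile 36.5 (-0.36 to 0.32). The median became 0.01 log2 when scaled to the 75th percentile of all human miRNAs. The largest differences among the 6 were -0.41 log2 for miR-145, 0.36 log2 for miR-107, -0.26 log2 for miR-34b and -0.24 log2 for miR-34c-5p.

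The medians of the other families lay nearer to equality than that of let-7. In the miR-17 to 92 family clusters, which promote proliferation, 10 of 14 members were lower, 3 higher and 1 equal, and the median was -0.17 log2 at percentile 6.91 (-0.21 to 0.18). Scaled to the 75th percentile of all human miRNAs, 9 were lower and 5 higher, with a median of -0.051 log2. Besides miR-363, miR-18b differed by -0.99 log2, to a treated value of 2.51 log2, under the level of full detection. miR-92a differed by -0.55 log2 and miR-19a by -0.50 log2. Of this list, miR-92a-1* was above the floor in the untreated library only, as given above. A further 2 arms were above the floor in the treated library only, of which 0 were flagged as detected. All 5 measured members of the miR-23/27/24 clusters were lower, with a median of -0.14 log2 at percentile 5.85 (-0.20 to 0.27), although 1 was higher when scaled to the 75th percentile of all human miRNAs. miR-27b differed by -0.32 log2, miR-23a by -0.21 log2, miR-27a by -0.14 log2 and miR-23b by -0.12 log2. In the miR-15/16 family 5 of 8 members were lower and 2 equal, with a median of -0.13 log2 at percentile 27.2 (-0.32 to 0.26), but 4 were lower and 4 higher, with a median of -0.015 log2, under that scaling. Besides miR-503, miR-16-2* and miR-15b*, which were not flagged as detected, miR-195 differed by 0.50 log2. The miR-29 family, which targets collagen and DNA methyltransferase transcripts, had 4 of 5 members lower and a median of -0.06 log2 at percentile 40.9 (-0.37 to 0.32), which became 0.05 log2 under the same scaling. miR-29a* was not flagged as detected. miR-29b differed by -0.27 log2, miR-29a by 0.12 log2 and miR-29b-1* by -0.06 log2.

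Clusters under imprinting or restricted to germ cells and placenta were mostly below the floor. Of 47 arms of the chromosome 19 imprinted cluster, 42 were above the floor on neither array and 5 in the treated library only, with treated values too low for a bound. Of 65 arms of the chromosome 14 imprinted cluster, 61 were above the floor on neither array. The 2 measured on both were miR-134 and miR-494 (7.10 log2 untreated and 7.81 log2 treated), and 2 were above the floor in the untreated library only. In the X chromosome testis cluster 15 of 20 arms were above the floor on neither array; miR-513a-5p was above the floor on both but not flagged as detected, 3 were above the floor in the treated library only and 1 in the untreated library only. Of 15 embryonic stem cell arms, 9 were above the floor on neither array; miR-371-5p was higher as given above, miR-367*, under the level of full detection on both arrays, differed by -0.97 log2, and 2 arms were above the floor in each library alone.

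Lists of tissue markers held few measured members. Of 11 liver-enriched arms 7 were above the floor on neither array, among them miR-122, the most abundant miRNA of hepatocytes, named here after its values were seen. miR-148a was 3.60 log2 untreated and not flagged as detected on the treated array. miR-192 and miR-215, the second of which was not flagged as detected, were above the floor in the treated library only, and miR-885-3p in the untreated library only. The 3 of 18 epithelial arms measured on both arrays were miR-200b (-0.48 log2), miR-183 (-0.25 log2) and miR-96 (-0.08 log2), and 1 more was above the floor in the treated library only. miR-126, carried by the endothelial gene EGFL7 and not flagged as detected, and miR-145 (-0.41 log2) were the 2 measured of 11 mesenchymal and vascular arms. In the neuronal list, besides miR-129-3p, miR-128 differed by 0.54 log2 and miR-137 by 0, and 2 of its 15 arms were above the floor in the treated library only. Of the 11 blood cell arms only miR-150* was measured on both, and 1 was above the floor in the treated library only. Of 8 muscle arms 7 were above the floor on neither array, and miR-133a was above the floor in the treated library only, without being flagged as detected. Among fragments of other RNA classes, miR-768-5p and miR-768-3p differed by 0.69 log2 (from an untreated value of 3.16 log2) and 0.53 log2, opposite in direction to miR-886-3p.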

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

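The array also carries probe sets for viral miRNAs, which the value table used here did not hold and which entered no comparison. On the treated array 6 of 76 viral probe sets were flagged as detected, in a cell line with no stated infection; the median of all 76 was 0.168 intensity units. The highest was kshv-miR-K12-3 at 44.9 intensity units (error 3.69), followed by hsv1-miR-LAT at 15.2 (error 1.20). ebv-miR-BART13 gave 8.03, ebv-miR-BART12 6.55, ebv-miR-BHRF1-1 2.46 and ebv-miR-BHRF1-3 1.86. These signals come from 1 array, and 4 of the 6 were below 10, the range in which many of the human miRNAs that differed by 2-fold also lie. The 95th percentile of the viral sets was 4.94 intensity units, or 3.39 on the log2 scale of the value table. No explanation for them was tested.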

How the results depend on the processing

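No paired analysis was possible because each group had 1 library. All scaling and threshold alternatives were planned; floors at the untreated lowest measured value, at the viral 95th percentile and at the level from which every miRNA was flagged as detected were chosen after seeing the data. No called direction reversed under any of them, but this was largely set in advance. Scaling to a percentile or median shifted every difference by at most 0.11 log2, while a call needs 2-fold. Floors and thresholds drop miRNAs and leave the differences of the others as they were. A floor 4 times higher left 2 higher and 3 lower miRNAs, 121 on both arrays and 13 in the treated library only. Both the floor at the viral 95th percentile and the floor of full detection gave 2 higher, 5 lower and 14 in the treated library only, and the untreated lowest measured value gave 29 in the treated library only. These follow from construction, since fewer dim miRNAs enter. Under those 3 higher floors, and with the strongest arm of each member, the median of the fragments of other RNA classes was 0. Quantile normalization of the 2 columns gave 6 lower, 31 in the treated library only and 31 in the untreated library only. The equal counts follow from construction, because both columns then hold the same values. Why fewer were lower was not tested. A threshold of 1.5-fold gave 14 higher and 26 lower, and 3-fold gave 4 higher and 2 lower, which turns the split. The 4 higher were miR-602, miR-371-5p, miR-135a* and miR-874, whose bounds against the level of full detection were at most 2.71-fold. Of the 2 lower, miR-503 was not flagged as detected and had a bound of 1.65-fold. The turn therefore rests on values under that level. A pseudocount equal to the floor gave 19 higher and 21 lower, because miRNAs at the lowest value on 1 array then enter. The other recomputed counts stayed within 1.5 times, and list medians moved by less than the members' median spot error on 2 arrays. With normexp the 6 highest miRNAs held 56.6% of the treated level, against 55.2% as deposited and 65.4% of the scanner's total gene signals. Below 5 log2 simulated spot error alone gave 7 differences of 2-fold (central 95%, 3 to 12) against 14 measured, and at 5 log2 or more 0 (0 to 1) against 3. Both simulated arrays shared the treated array's lowest measured value, so the counts below 5 log2 are not like for like.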

Other observations

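All tests in this part were chosen after the results were seen.

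Of 26 star arms above the floor on both arrays 19 were lower and 5 higher, 6 of them lower by 2-fold (2 of these not flagged as detected on the treated array) and 2 higher by 2-fold, and their median was -0.22 log2, at percentile 10.2 of matched random lists (-0.31 to 0.09), so as a class they lay within the range of other miRNAs of their level. In 9 of 14 pairs with both arms measured the star arm's difference was below that of its partner, with a median of star minus partner of -0.26 log2. The star arm was not flagged as detected on the treated array in 5 of these pairs, and among the other 9 it was below its partner in 5. miR-21* against miR-21 was the widest pair, at -2.21 log2. As the highest miRNA of both arrays, miR-21 had its difference set at 0 by the normalization, so this width is that of miR-21* alone. The next was miR-181a* against miR-181a at -1.11 log2, while miR-22*, under the level of full detection on both arrays, went the other way at 0.69 log2.

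All 6 miRNAs that were 2-fold higher are read by probes with targets of 15 bases or fewer, as are 42 of all miRNAs measured on both arrays and 3 of the 11 lower ones. A common shift of all short-target probes that alone made the 6 differences would bring the class median to the smallest of these, 1.09 log2. The 42 had a median of 0.084 log2 and an upper quartile of 0.44 log2, which argues against a common shift of that size. A smaller common shift that adds to the scatter of dim miRNAs was not tested and stays open. A common added signal on dim short-target probes stays open. The 25 with an untreated level under 5 log2 had a median of 0.26 log2 and an upper quartile of 0.51 log2, short of the 6. Of the 25, 15 were higher, against 24 of 70 dim long-target miRNAs with a median of -0.21 log2. The median of the whole short class was at percentile 99.0 of matched random lists (-0.24 to 0.05). The 25 and the 42 both include the 6 that raised the question, so part of this contrast comes from how the 6 were picked. The base composition of the short-target probes and an effect of the drug also stay open, and neither was tested.

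More miRNAs were above the floor in the treated library only (59) than in the untreated library only (24). A candidate explanation is that the arrays were read down to different lowest measured values, 2.25 log2 untreated and 1.36 log2 treated. With both read from 2.25 log2 upward the counts were 29 and 33. The normalization gave both columns nearly the same values, so near-equal counts above a shared level were largely set in advance. The result therefore cannot tell that difference from a gain of miRNAs with treatment. The excess by itself gives no ground for claiming a general gain. Why the lowest measured values differ was not tested.

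The let-7 family was higher as a group. A level-dependent difference between the arrays was 1 candidate explanation. The 27 others at 8 log2 or more had a median of -0.057 log2 and an upper quartile of 0.02 log2. The 7 let-7 members in that range had a median of 0.34 log2, so they rose in rank against other bright miRNAs. Where rank sets the value, a rise of some bright miRNAs is matched by a fall of others. The comparison therefore cannot count for or against a level-dependent difference. Whether the signal is shared between near-identical members, so that a change in 1 of them could raise several, cannot be told apart from a change in each, because let-7f-1*, which has a sequence of its own, differed by 0.92 log2 from a dim untreated value, while let-7b* was not flagged as detected on the treated array. An effect of the drug and a difference between cultures both stay open with 1 library per group.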
